A study of Mus musculus with 10 samples.

How the data were processed

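RNA was measured in 10 libraries of mouse embryonic stem (ES) cells from a C57BL/6 background, 1 library for each condition and day. Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with the SOLiD total RNA-seq kit and sequenced on a SOLiD instrument. The knockout removed a floxed exon of Tet3 by transient expression of Cre recombinase, per the labels. Each library was mapped to its condition by its title, and every column of the table matched 1 title.

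The authors deposited 1 table of RPKM values (reads scaled by transcript length and by library total), rounded to 2 decimals, for 21937 gene symbols. The submitters' processing notes name HTSeq, a read counter, and the mouse build mm9. The aligner, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Values of genes with close paralogs, of overlapping genes and of antisense genes are uncertain for that reason. RPKM divides by the library total, so a rise of very abundant transcripts lowers all others. The 10 most abundant genes held 4.88% to 9.40% of the summed RPKM of a library.

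RPKM values are not counts, and no count model was run on them. Sequencing depth was estimated from the table itself. Where 1 read is counted, a gene's RPKM is a whole multiple of a step set by its length and the library total. For 3932 genes with a single annotated transcript in GENCODE vM21, used for transcript lengths only, values up to 1 RPKM were set against the steps that each possible total would give. At the chosen totals 59.7% to 73.6% of these values came within 0.15 read of a whole number, against 25.4% to 43.8% at wrong totals near the chosen ones. The totals were chosen for nearness to whole reads on these same values, so a higher share there follows from the choice and is no separate check. The totals came to 43800000 reads for control cells on day 4, 22300000 for Tet3-overexpressing cells on day 4, 27300000 for control on day 7 and 17400000 for overexpression on day 7. In the SFEB culture they were 10200000, 10300000 and 10600000 for wild type, knockout and knockout with Dkk on day 6, and 11300000, 11000000 and 37200000 on day 10. For the Dkk-treated knockout on day 10 a total of 75800000, about 2 times the chosen total, gave a higher mean cosine of the distance to whole reads (0.584 from 87 values, against 0.471 from 172), so the depth of that library is the least certain, and it exceeds that of the other SFEB libraries at either total. Whole multiples of a true total also give whole reads, and the smallest fitting total was kept. These are estimates, since the lengths come from another annotation than the one the authors used. A median transcript length was found for 98.3% of symbols, 1914 of them through an older symbol. From estimated reads, 95% Clopper-Pearson intervals of the ratio of 2 libraries were computed, which cover counting error only and carry no pseudocount.

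Ratios were computed as log2(RPKM + 0.5) of 1 library minus that of another, so the change of genes with low values is understated. Genes at 1 RPKM or more in at least 1 library of a culture were compared, 12912 in the SFEB culture and 12387 in the FBS culture, and a gene was counted as changed at 2-fold or more. Counts on both days of a culture were set beside the product expected of independent lists. Some counts of genes changed in opposite directions also exceeded that product, so an excess over it is a description and not a test. With 1 library per condition and day there is no test of a single comparison.

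Of 25 gene lists chosen before the data were examined, with 418 gene names, 1 gene was not listed in the table and 6 were matched through an older symbol in the RefSeq table. The lists cover pluripotency, neural progenitor, neuron, primitive streak and early mesoderm, cardiac, endoderm, neural crest, epidermis and surface ectoderm, endothelium and blood, fibroblast and matrix, Wnt target, secreted Wnt antagonist, Wnt ligand, posterior Hox, DNA methylation machinery, imprinted, germline genes silenced by DNA methylation, TGF-beta and BMP response, Notch pathway, cell cycle, p53 and stress, immediate early, hypoxia and glycolysis, housekeeping and sex-linked marker genes. A list with at least 5 members above the filter was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the central 95% of random lists is called outside the random range. In 2000 simulated lists of 15 unchanged genes on the day 6 knockout ratios of 12912 genes, 4.75% fell outside the random range, and of lists raised by 0.5 on the log2 scale 99.9% did. The unchanged lists came from the same ratios as the random lists, so their share follows from the method. Genes of a marker list can change together, which random lists do not reproduce. The simulation therefore does not calibrate the calls of marker lists.

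An additive model was fitted with limma to log2(RPKM + 0.5) of all 10 libraries, for 13041 genes at 1 RPKM or more in at least 2 libraries. It has a term for each of the 4 combinations of culture and day and 1 coefficient each for knockout, Dkk and overexpression, which leaves 3 residual degrees of freedom. The residual measures how far an effect differs between the 2 days of a culture and is not a spread between replicates. P-values were adjusted by the Benjamini-Hochberg method at 0.05. On simulated data for the knockout coefficient, with 12646 genes, the model recovered 23 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, with 17 false calls. Simulated genes sat at their culture mean with 1 level of noise beyond counting error and a knockout effect equal on both days. Effects that differ between days were not simulated, so these rates do not carry over to the real libraries.

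Comparisons that share a library have opposite or equal errors by construction. The knockout and the Dkk ratio share the untreated knockout library, so genes selected by the knockout ratio on 1 day were followed in the Dkk ratio of the other day, which shares no library, and set against 2000 expression-matched gene sets.

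Genes named in the report follow a rule set before the data were examined. It takes Tet1, Tet2 and Tet3, the 12 genes with the largest smaller change of both days in each direction among those at 5 RPKM or more, and up to 4 members of each list with the largest mean change. Symbols of small RNAs, of predicted genes and of unnamed clones were counted but not named. Genes named outside the rule are marked as chosen after their values were seen. Alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 5 RPKM, median-ratio scaling, scaling to a common sum (TPM), a 4-fold threshold, a counting interval that excludes equality, a limma prior with trend and limma on 1 culture alone. Gene order for neighbours was taken from the RefSeq table of assembly GRCm38.p6, and no coordinates are given because its assembly differs from mm9. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.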

Results

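Total RNA of differentiating mouse ES cells was profiled in 10 libraries, 1 for each condition and day. In the SFEB culture, a serum-free culture of floating aggregates that leads ES cells towards neuroectoderm, the embryonic source of the nervous system, 6 libraries came from wild-type cells, Tet3 knockout cells and Tet3 knockout cells given Dkk, each on day 6 and day 10. Tet3 is an enzyme that oxidises methylated cytosine in DNA, and Dkk proteins are secreted inhibitors of Wnt signalling. In a culture with fetal bovine serum (FBS), in which neural differentiation is not favoured, 4 libraries came from control and Tet3-overexpressing cells on day 4 and day 7. Estimated depth was 10200000 to 11300000 reads in 5 SFEB libraries, 37200000 in the Dkk-treated knockout on day 10, and 17400000 to 43800000 in the FBS libraries. Between 11028 and 12152 genes reached 1 RPKM in a library. No condition was replicated within a day, so each difference is between single libraries, and the other day of the same culture is the one check on it. The labels name no further line of cells of any genotype, so genotype and line are not separated.

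Tet3 was listed at 8.11 RPKM in wild type, 6.59 in the knockout and 7.64 in the knockout with Dkk on day 6, and at 10.2, 14.3 and 13.1 RPKM on day 10. The knockout removed a single exon and the table gives whole-gene values, so these numbers do not check the genotype. In the FBS culture Tet3 stood at 0.96 RPKM in control and 12.5 in overexpressing cells on day 4, and at 5.87 and 14.1 RPKM on day 7, log2 ratios of 3.16 and 1.20. Control cells thus held more Tet3 transcript on day 7 than on day 4. Tet1 went from 2.74 RPKM in wild type to 2.94 in the knockout on day 6 and from 2.47 to 2.33 on day 10, and Tet2 from 0.93 to 1.04 and from 3.21 to 3.54 RPKM. With overexpression Tet1 was higher by 0.54 on day 4 and 1.47 on day 7, and Tet2 by 0.84 and 0.50, on the log2 scale.

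**Figure D1:**
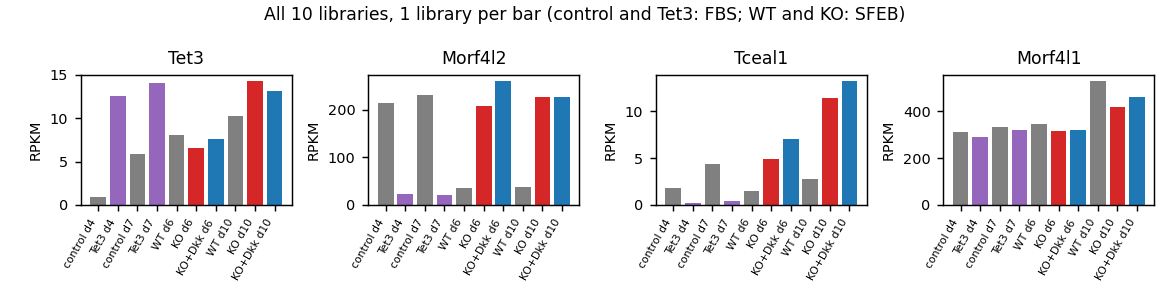
RPKM (y axis, linear from 0) of Tet3, Morf4l2, Tceal1 and Morf4l1 in all 10 libraries (x axis), 1 library per bar, with control and wild type in grey, Tet3-overexpressing cells in purple, Tet3 knockout in red and Tet3 knockout with Dkk in blue. Tet3 stands at 0.96 RPKM in control cells on day 4 and at 12.5 in overexpressing cells, and Morf4l2 at 214.6 and 23.1 RPKM there and at 36.3 RPKM in wild type and 207.5 in the knockout on day 6.

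The first question was which genes differ between Tet3 knockout and wild-type cells under conditions that favour neural differentiation. Posterior Hox genes, which set position along the hindbrain, spinal cord and trunk, had the largest median change of the lists on both days. Of 24 members above the filter, 22 were at least 2-fold higher in the knockout on day 6 and 21 on day 10, with 0 lower on either day. The median log2 ratio was 3.07 on day 6 and 3.96 on day 10, above all 10000 matched random lists. Hoxb9 was at 0.51 RPKM in wild type and 60.7 in the knockout on day 6, and at 0.72 and 85.5 RPKM on day 10, with log2 ratios of 5.92 and 6.14. Hoxb8 went from 0.52 to 17.3 RPKM and from 0.40 to 43.8 RPKM, and Hoxa5 from 0.31 to 9.58 and from 0.47 to 34.9 RPKM. Aldh1a2, which makes retinoic acid, ranked highest by the smaller of its ratios on both days, at 0.39 RPKM against 74.2 on day 6 (log2 6.39, 95% counting interval of the read ratio 6.64 to 8.70) and 0.70 against 77.7 on day 10 (log2 6.03, interval 6.13 to 7.55).

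On day 6, 17 of 24 primitive streak and early mesoderm genes were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.61, above all random lists. Meox1, a regulator of somites, went from 0.27 RPKM in wild type to 161.6 in the knockout, Tcf15 from 0.11 to 44.9 and Foxc2 from 0.11 to 21.3 RPKM. On day 10 the median of that list was 0.52, with 11 members higher and 2 lower, inside the random range at percentile 95.9. Cardiac genes had medians of 0.78 on day 6 and 1.98 on day 10, both above the random range, with 9 and 15 of 19 members at least 2-fold higher. Actc1, a muscle actin, went from 1.83 to 10.2 RPKM on day 6 and from 2.28 to 54.5 RPKM on day 10. Fibroblast and matrix genes moved from a median of 0.41 on day 6, with 4 of 15 members higher, to 2.07 on day 10, with 14 of 15 higher. The collagen gene Col3a1 was at 0.88 RPKM in wild type and 2.61 in the knockout on day 6, and at 20.5 and 381.8 RPKM on day 10.

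Neural progenitor genes had a median log2 ratio of -0.67 in the knockout on day 6, below all random lists, with 7 of 23 members at least 2-fold lower and 0 higher. On day 10 the median was 0.12, inside the random range, with 2 higher and 2 lower. The 1 member at least 2-fold lower on both days was Otx2, a regulator of forebrain and midbrain, which went from 32.0 RPKM in wild type to 5.27 in the knockout on day 6 and from 26.3 to 7.10 RPKM on day 10. Among the genes lower on both days, Tal2 went from 18.9 to 1.27 RPKM and from 14.7 to 2.56 RPKM, Pax7 from 11.6 to 2.74 and from 9.07 to 3.68 RPKM, and Lmx1b from 8.27 to 2.78 and from 12.1 to 4.87 RPKM. All 3 encode transcription factors. Gpm6a, which encodes a neuronal membrane glycoprotein, went from 6.81 to 2.58 RPKM and from 203.1 to 50.1 RPKM. Neuron genes had a median of -0.47 on day 6, below the random range, and 0.12 on day 10, inside it. On day 6, 2 of 24 members were at least 2-fold higher and 3 lower, and on day 10, 3 were higher and 0 lower. Neurog2, a regulator of neuron formation, went from 0.44 to 1.96 RPKM and from 6.31 to 20.9 RPKM, and the Notch ligand gene Dll3 from 2.99 to 13.8 and from 10.9 to 22.2 RPKM. Wnt1, expressed at the midbrain border, was at 21.1 RPKM in wild type and 1.02 in the knockout on day 6, and at 0.59 and 0.81 RPKM on day 10.

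**Figure D2:**
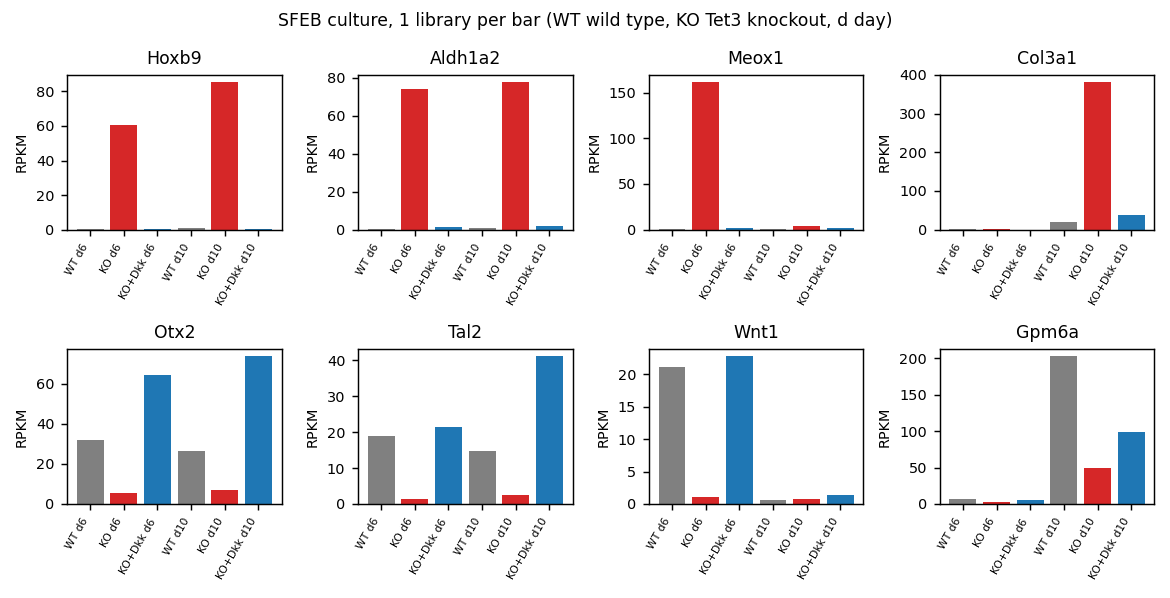
RPKM (y axis, linear from 0) of 8 genes in the 6 SFEB libraries (x axis), 1 library per bar, with wild type in grey, Tet3 knockout in red and Tet3 knockout with Dkk in blue. Hoxb9 stands at 60.7 and 85.5 RPKM in the untreated knockout and at 0.10 and 0.46 RPKM with Dkk, and Otx2 at 5.27 and 7.10 RPKM without Dkk and 64.2 and 73.6 RPKM with it.

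Pluripotency genes had medians of -0.28 and -1.22, both below the random range, with 10 of 16 members at least 2-fold lower on day 10. Pou5f1 was at 35.8 RPKM in wild type and 36.6 in the knockout on day 6, and at 20.3 and 3.06 RPKM on day 10. Imprinted genes had a median of 0.61 on day 6, above all random lists, and 0.03 on day 10, inside the range. Igf2, a fetal growth factor, went from 10.5 to 175.7 RPKM and from 60.4 to 308.7 RPKM, and its neighbour H19 from 3.74 to 57.0 and from 11.8 to 61.8 RPKM. Endoderm genes had medians of 1.12 and 0.02, and epidermis and surface ectoderm genes 1.33 and -0.48, the latter outside the random range on both days in opposite directions. Wnt target genes had a median of 0.52 on day 6, above the random range, and 0.32 on day 10, inside it, and secreted Wnt antagonists 0.47 and 0.21 with the same calls. Wnt ligands, at 0.04 and 0.43, lay inside it on both days. Of 16 Wnt target genes, 6 were at least 2-fold higher on day 6 and 1 lower, with Cdx1 (log2 3.79), Cdx2 (3.98) and Cdx4 (2.66) among the higher. The endothelium and blood list had a day 6 median of 0.60 with 4 of 12 members higher and 2 lower, outside the random range, but -0.01 with the filter at 5 RPKM. Hypoxia and glycolysis genes had medians of 0.29 and 0.79, both above the range, TGF-beta and BMP response genes 0.33 and 0.02, above it on day 6, and Notch pathway genes 0.15 and 0.54, above it on day 10. Cell cycle genes had medians of -0.06 and -0.39, below the range on day 10 with 0 of 16 members changed 2-fold. Housekeeping genes, chosen as a control, had medians of 0.20 on both days, outside the range on day 6, with Gusb 2-fold higher on both days. Neural crest, DNA methylation machinery, p53 and stress, and immediate early genes lay inside the random range on both days. The call of pluripotency genes on day 6 ended with no filter (median -0.15) and with a filter of 5 RPKM (-0.05), that of epidermis and surface ectoderm genes on day 10 with no filter (-0.16), that of TGF-beta and BMP response genes on day 6 with a pseudocount of 0.1 (0.39), and that of Notch pathway genes on day 10 with a filter of 5 RPKM (0.40). Only 3 germline genes reached 1 RPKM in this culture, Rhox6, Rhox9 and Ddx4. Rhox6 went from 6.90 to 1.45 RPKM on day 6 and from 5.80 to 1.27 RPKM on day 10. The 5 sex-linked marker genes did not reach 1 RPKM in any library.

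In all, 630 genes were at least 2-fold higher and 282 lower in the knockout on day 6, and 1067 higher and 253 lower on day 10, of 12912 compared. Both days shared 272 higher genes, against 52.1 expected of independent lists, and 48 lower genes, against 5.5. A further 29 genes were higher on day 6 and lower on day 10, against 12.3 expected, and 14 the reverse, against 23.3. The log2 ratios of both days correlated across genes with Pearson's r of 0.41, where genes are not independent replicates. In the additive model limma called 15 genes higher and 2 lower in the knockout, led by Hoxb9 (log2 6.03, SE 0.18, adjusted p = 0.00122), Fndc5 (3.66, SE 0.17, adjusted p = 0.00633), Aldh1a2 (6.21, SE 0.33, adjusted p = 0.00671) and Vtn, which encodes vitronectin (3.35, SE 0.17, adjusted p = 0.00671), each higher on both days. Vtn was chosen after its values were seen. With TPM scaling the 282 lower genes of day 6 became 469 and the 48 of both days 77, and with a pseudocount of 0.1 they became 542 and 101. TPM scaling also lessens the weight of the pseudocount. The model's calls depend on the setting, with 103 higher and 10 lower in the SFEB culture alone and 0 without the expression filter, where 2276 genes had an unadjusted p under 0.05.

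The second question was how Dkk changes the knockout culture. Posterior Hox genes stood far lower with Dkk, with 24 of 24 members at least 2-fold lower on day 6 and 23 of 24 on day 10, and median log2 ratios of -3.30 and -4.01. Hoxb9 went from 60.7 RPKM in the untreated knockout to 0.10 with Dkk on day 6 and from 85.5 to 0.46 RPKM on day 10. Aldh1a2 went from 74.2 to 1.41 RPKM and from 77.7 to 2.15 RPKM. Otx2 went from 5.27 to 64.2 RPKM on day 6 (log2 3.49, 95% counting interval 3.22 to 4.03) and from 7.10 to 73.6 RPKM on day 10 (log2 3.29, interval 3.06 to 3.72), Tal2 from 1.27 to 21.3 and from 2.56 to 41.2 RPKM, and Emx2, a cortical regulator, from 1.01 to 5.20 and from 0.99 to 7.55 RPKM. Rspo2, which encodes a secreted enhancer of Wnt signalling, went from 0.32 to 7.97 RPKM and from 1.89 to 40.9 RPKM.

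Primitive streak and early mesoderm genes had a median of -1.30 with Dkk on day 6, with 14 of 24 members at least 2-fold lower and 0 higher, and -0.38 on day 10, inside the random range at percentile 3.06. Meox1 went from 161.6 to 1.44 RPKM on day 6. Fibroblast and matrix genes had medians of -0.35 and -2.29, with 14 of 15 members lower on day 10, where Col3a1 went from 381.8 to 37.2 RPKM. Cardiac genes had medians of -0.65 and -0.85 with 8 of 19 lower on each day, and endothelium and blood genes -0.73 and -0.99. Neural progenitor genes had a median of 0.74 on day 6, above all random lists, with 10 of 23 members higher, and 0.13 on day 10, inside the range. Imprinted genes had medians of -0.48 and -0.20, both below the range, with Igf2 going from 175.7 to 23.0 RPKM and from 308.7 to 71.8 RPKM.

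Wnt target genes had medians of -0.31 and -0.26 with Dkk, both below the random range, with 3 of 16 members higher and 4 lower on day 6. Among the lower members on day 6 were Cdx1 (log2 -3.39), Cdx2 (-3.56) and Cdx4 (-2.66). Cdx2 went from 20.4 RPKM to 1.27 on that day. Axin2, a member of the list and a negative-feedback gene of the pathway, went the other way, from 10.3 to 32.7 RPKM. On day 10 Axin2 went from 10.1 to 12.8 RPKM. Apcdd1, another inhibitor of the pathway, went from 9.57 to 80.9 RPKM on day 6. Secreted Wnt antagonists had medians of -0.38 and -0.45, below the range, and Wnt ligands 0.30 and 0.09, above it on day 6, with Wnt8b going from 0.77 to 13.7 RPKM and from 1.06 to 14.4 RPKM. Cell cycle genes were inside the range on day 6 and above it on day 10, with a median of 0.32 and 0 of 16 members changed 2-fold. Epidermis and surface ectoderm genes (-1.26) and TGF-beta and BMP response genes (-0.42) lay below the range on day 6 and inside it on day 10. Neuron (-0.14), Notch pathway (-0.39), immediate early (-0.55) and hypoxia and glycolysis genes (-0.16) lay below it on day 10 and inside it on day 6. Pluripotency, endoderm, neural crest, DNA methylation machinery, p53 and stress, and housekeeping genes lay inside it on both days. With a filter of 5 RPKM the calls of endothelium and blood genes ended on both days, at medians of -0.50 and -1.08, and those of cardiac (-1.05) and Wnt target genes (-0.26) on day 10, where these medians were no nearer to 0. The Wnt target call on day 10 also ended with a pseudocount of 1 (-0.18) and with no filter (-0.16), and that of secreted Wnt antagonists on day 10 with no filter (-0.22).

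With Dkk, 282 genes were higher and 461 lower on day 6, and 220 higher and 675 lower on day 10. Both days shared 47 higher genes, against 4.8 expected, and 201 lower genes, against 24.1. In opposite directions, 21 genes were higher on day 6 and lower on day 10, against 14.7 expected, and 10 the reverse, against 7.9. The additive limma model called 2 genes higher, Wnt8b (log2 3.37, SE 0.24, adjusted p = 0.0292) and Fezf1 (2.20, SE 0.16, adjusted p = 0.0314), and 9 lower, among them Hoxb9 (-6.58, SE 0.18, adjusted p = 0.000739), Aldh1a2 (-5.09, SE 0.33, adjusted p = 0.0207) and 4 further Hox genes, each in the same direction on both days. Fezf1 was chosen after its values were seen. With a pseudocount of 0.1 the 282 higher genes of day 6 became 471, and both days shared 78 higher and 320 lower genes. The SFEB culture alone gave 9 higher and 37 lower, and no expression filter gave 0, with 1110 genes at an unadjusted p under 0.05.

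Knockout and Dkk changes were also set side by side across days, where they share no library. The 630 genes higher in the knockout on day 6 had a median log2 change of -0.63 with Dkk on day 10, against -0.10 for matched genes, and 78.3% of them were lower against 58.5% of matched genes. The 1067 genes higher on day 10 had a median of -0.19 with Dkk on day 6, against 0.00, also below all matched sets. With Dkk these genes stayed above wild type on the other day, the 630 with a median of 0.12 on day 10, at percentile 98.8 of matched sets, and the 1067 with 0.22 on day 6, above all matched sets, where the untreated knockout had 0.78 and 0.49. For the 282 genes lower on day 6 the median Dkk change on day 10 was 0.15, above all matched sets. For the 253 lower on day 10 it was 0.00 on day 6, inside the matched range at percentile 62.9, but 0.058 and outside it with a filter of 5 RPKM. Compared with wild type, the Dkk-treated knockout had a posterior Hox median of -0.23 on day 6, below the random range, and -0.20 on day 10, inside it. Primitive streak and early mesoderm genes (0.47 and 0.39) and Wnt ligands (0.59 and 0.86) lay above the range on both days. On day 6 endoderm genes (0.69), Wnt target genes (0.33) and secreted Wnt antagonists (0.33) lay above it and neuron (-0.39) and neural crest genes (-0.28) below it. On day 10 neural progenitor (0.52), fibroblast and matrix (0.57) and hypoxia and glycolysis genes (0.60) lay above it and epidermis and surface ectoderm genes (-0.37) below it. The cardiac list remained higher than in wild type on day 10, above all random lists with 13 of 19 members at least 2-fold higher. Its median there was no lower than that of the untreated knockout against wild type, 1.98 with 15 members at least 2-fold higher. Pluripotency genes lay below the range at -0.50 and -1.08. With a filter of 5 RPKM the day 6 pluripotency median turned to 0.37, above the random range. The day 10 calls of primitive streak and early mesoderm (0.39) and of fibroblast and matrix genes (0.42) ended with that filter, the former also with a pseudocount of 0.1 (0.44), and that of epidermis and surface ectoderm genes with no filter (0.07). In all, 330 genes differed 2-fold between Dkk-treated knockout and wild type on day 6 and 810 on day 10, against 912 and 1320 between untreated knockout and wild type. Dkk-treated and untreated knockout differed in 743 and 895 genes.

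**Figure D3:**
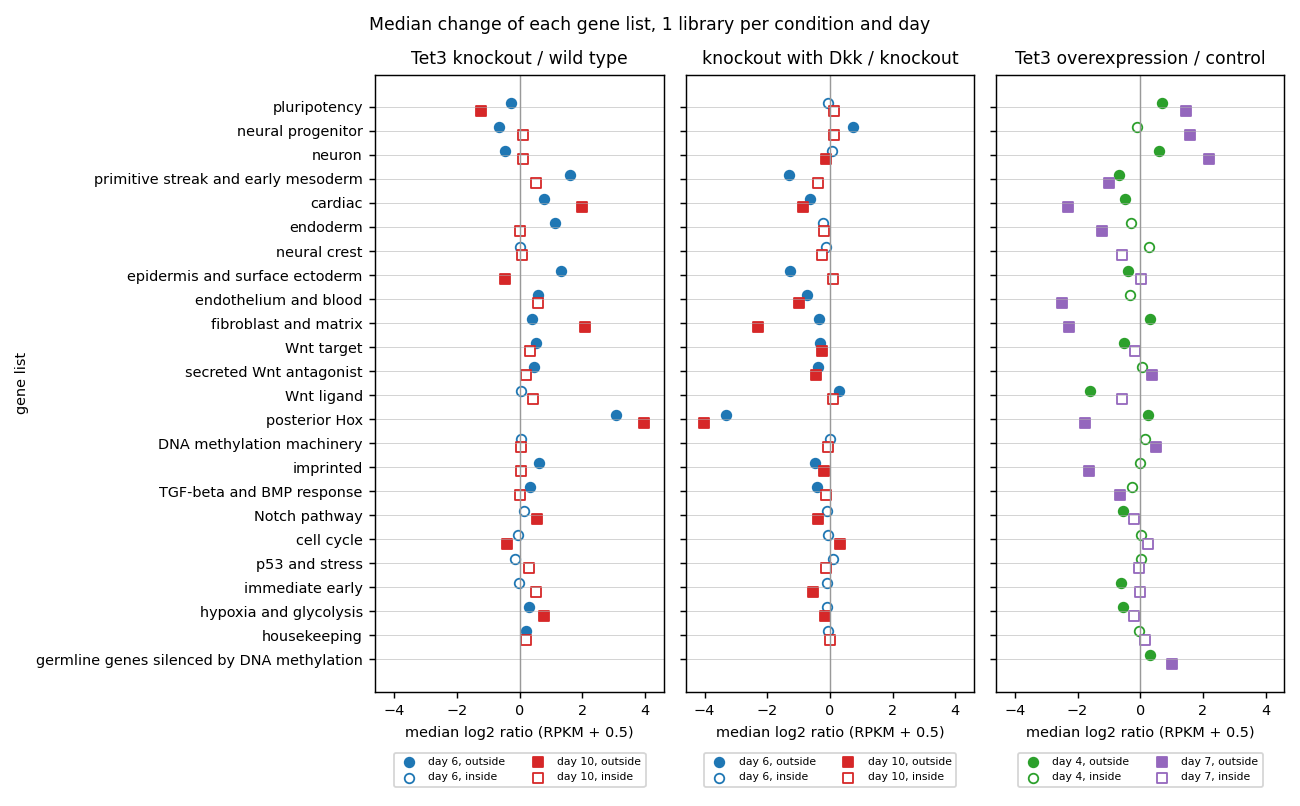
Median log2 ratio of RPKM + 0.5 (x axis) of each gene list (y axis) in the 3 comparisons, with 1 marker per day, filled where the median lies outside the central 95% of 10000 matched random lists and open where it lies inside. Posterior Hox genes lie at 3.07 and 3.96 in the knockout and at -3.30 and -4.01 with Dkk, and neuron genes at 0.61 and 2.21 with Tet3 overexpression.

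The third question was which genes Tet3 overexpression changes where serum holds back neural differentiation. Sox1, an early neural transcription factor, went from 1.24 RPKM in control to 16.3 in overexpressing cells on day 4 (log2 3.27, 95% counting interval 3.53 to 3.91) and from 0.05 to 5.61 RPKM on day 7 (log2 3.47, interval 5.67 to 8.05). Pax6 went from 1.57 to 5.71 and from 0.33 to 3.47 RPKM, and Tubb3, a neuronal tubulin, from 18.0 to 69.2 and from 6.37 to 42.8 RPKM. Neuron genes had a median log2 ratio of 0.61 on day 4 and 2.21 on day 7, above all random lists, with 2 and 10 of 13 members at least 2-fold higher. Of 24 listed neuron genes, 13 passed the filter in FBS. In control these had a median of -1.43 from day 4 to day 7, with 9 at least 2-fold lower and 1 higher. Tubb3 and Sox1 were lower on day 7 than on day 4 in overexpressing cells too. The larger ratio on day 7 thus goes with a fall in control. Neural progenitor genes had a median of -0.09 on day 4, inside the range with 3 of 15 higher and 1 lower, and 1.57 on day 7 with 9 higher. Sox2, a member of that list, went from 51.2 to 86.3 and from 16.0 to 62.2 RPKM. In control the neural progenitor list had a median of -1.32 from day 4 to day 7, with 8 of 15 members lower and 1 higher.

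Pluripotency genes were higher with overexpression on both days, with medians of 0.71 and 1.45 and 5 and 14 of 22 members at least 2-fold higher. Nr0b1 went from 15.5 to 48.4 RPKM and from 4.73 to 24.7 RPKM, and Dppa4 from 46.5 to 99.2 and from 17.5 to 69.1 RPKM. Germline genes had medians of 0.31 and 1.03, above the range, with 3 and 5 of 9 members higher. The DNA methylation list, which holds Tet3 itself, had medians of 0.16, inside the range, and 0.50, above it. Dnmt3l went from 82.2 to 205.7 RPKM and from 29.3 to 127.0 RPKM. The metal-binding protein gene Mt1 went from 318.7 to 1234 RPKM on day 4 and from 364.5 to 1320 RPKM on day 7.

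Primitive streak and early mesoderm genes had medians of -0.66 and -0.99, both below the range, with 10 and 11 of 23 members lower and 1 and 8 higher. Wnt ligands had medians of -1.61 on day 4, below all random lists with 6 of 9 members lower, and -0.59 on day 7, inside the range. Wnt target genes had medians of -0.53, below it, and -0.18, inside it. T, the early mesoderm regulator also called Brachyury, went from 69.2 to 1.44 RPKM on day 4 and from 4.72 to 12.5 RPKM on day 7. Cdx2 went from 2.75 to 0.38 and from 44.9 to 0.93 RPKM, and Kdr, a receptor of vascular precursors, from 2.13 to 0.22 and from 36.3 to 5.05 RPKM. On day 7 cardiac genes had a median of -2.31 with 15 of 17 lower, endothelium and blood genes -2.50 with 13 of 16 lower, fibroblast and matrix genes -2.26 with 10 of 16 lower, posterior Hox genes -1.76 with 15 of 18 lower, and imprinted genes -1.62 with 14 of 21 lower. The day 4 medians of these 5 lists were -0.47, -0.31, 0.31, 0.24 and 0.00, in that order, and the cardiac median lay below the random range, those of the fibroblast and matrix and of the posterior Hox list above it, and the other 2 inside it. The embryonic globin gene Hbb-bh1 was at 2.01 and 0.29 RPKM on day 4, and at 4230 RPKM in control against 5.15 in overexpressing cells on day 7. Igf2 was at 31.5 and 17.8 RPKM on day 4, and at 1679 and 51.2 RPKM on day 7.

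**Figure D4:**
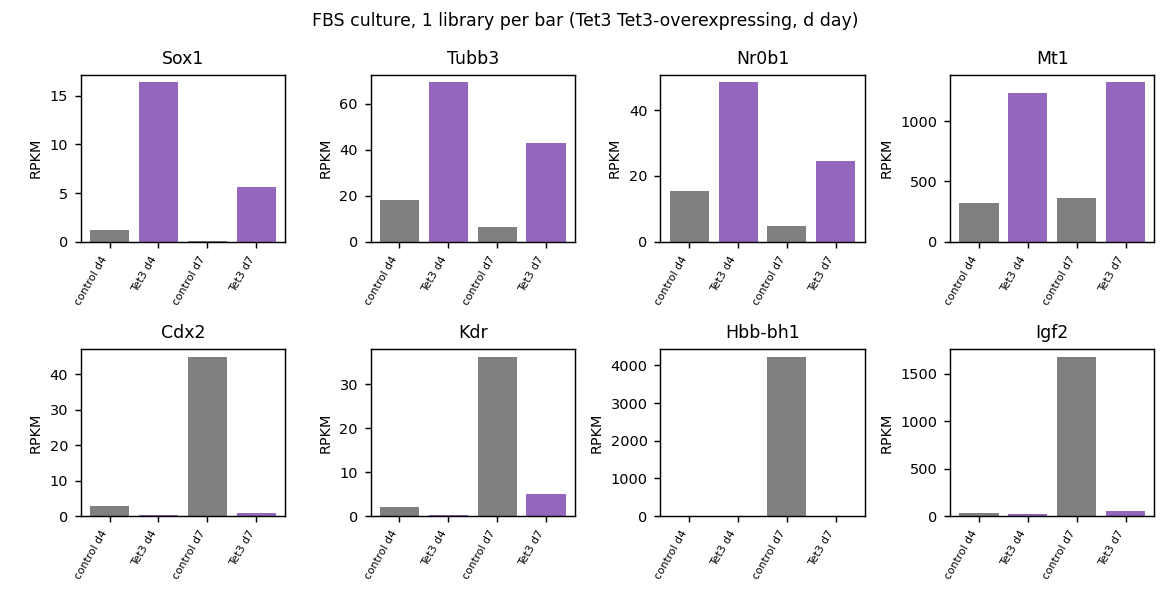
RPKM (y axis, linear from 0) of 8 genes in the 4 FBS libraries (x axis), 1 library per bar, with control in grey and Tet3-overexpressing cells in purple. Sox1 and Tubb3 are higher with overexpression on both days, while Hbb-bh1 reaches 4230 RPKM in control cells on day 7 and 5.15 RPKM in overexpressing cells.

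Endoderm genes had a median of -0.29 on day 4, inside the range, and -1.22 on day 7, below it, and TGF-beta and BMP response genes -0.26 and -0.64 with the same calls. Secreted Wnt antagonists lay inside it on day 4 and above it on day 7 at 0.36. Epidermis and surface ectoderm genes (-0.40), Notch pathway genes (-0.55), immediate early genes (-0.62) and hypoxia and glycolysis genes (-0.53) lay below the range on day 4 and inside it on day 7. Neural crest, cell cycle, p53 and stress, and housekeeping genes lay inside it on both days. With no filter the calls of primitive streak and early mesoderm genes on day 7 (-0.33) and of epidermis and surface ectoderm genes on day 4 (-0.07) ended, and with a pseudocount of 1 that of cardiac genes on day 4 (-0.27). With a filter of 5 RPKM those of primitive streak and early mesoderm (-0.99) and of endoderm genes (-1.32) on day 7 ended at medians no nearer to 0. The call of secreted Wnt antagonists on day 7 held with median-ratio scaling alone, with medians of 0.13 to 0.38 under the others. That scaling shifts a list and its random lists alike.

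With overexpression 213 genes were higher and 430 lower on day 4, and 862 higher and 1377 lower on day 7, of 12387 compared. Both days shared 100 higher genes, against 14.8 expected, and 113 lower genes, against 47.8. In opposite directions, 15 genes were higher on day 4 and lower on day 7, against 23.7 expected, and 47 the reverse, against 29.9. The log2 ratios of both days correlated across genes with r of 0.24. The additive limma model called 2 genes higher and 1 lower, Sox1 (log2 3.37, SE 0.17, adjusted p = 0.0108), an unnamed clone and Morf4l2 (-3.32, SE 0.17, adjusted p = 0.0108), each in the same direction on both days, and 2427 genes had an unadjusted p under 0.05. With a pseudocount of 0.1 the 430 lower genes of day 4 became 669 and both days shared 157 higher and 232 lower genes, and with TPM scaling 178 lower. The FBS culture alone gave 0 calls with 1208 genes at an unadjusted p under 0.05, and no expression filter gave 18 higher and 12 lower.

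Knockout and overexpression act on the same gene in opposite ways, in different cultures and on different days. The 227 genes higher in the knockout on both days that also passed the filter in FBS had a median log2 change of -1.52 with overexpression on day 7, against -0.08 for matched genes, with 85.9% lower against 54.3%. On day 4 their median was -0.16, inside the matched range at percentile 5.22, but -0.23 with a pseudocount of 0.1 and -0.24 with a filter of 5 RPKM, both outside it. The 28 genes lower in the knockout on both days had medians of 0.01 on day 4, inside the matched range, and 0.50 on day 7, above it at percentile 99.9. Their day 4 median lay outside the matched range with a pseudocount of 0.1 (0.47), with no filter (0.11) and with median-ratio scaling (0.20), and their day 7 median inside it with a pseudocount of 1 (0.14).

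From day 6 to day 10 in wild type, 23 of 24 neuron genes were at least 2-fold higher with a median of 2.85, and cell cycle genes had a median of -0.77. In all, 2185 genes were higher and 1031 lower. From day 4 to day 7 in control FBS cells, endoderm genes had a median of 3.08, endothelium and blood genes 2.73, cardiac genes 2.71, pluripotency genes -1.20 and neuron genes -1.43, and 1426 genes were higher and 1079 lower.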

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

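All tests in this part were chosen after the results were seen. With 1 library per condition and day, a list was taken up here where its medians lay outside the random range in opposite directions on the 2 days, and a gene that the rule names for a comparison where it changed at least 2-fold in opposite directions in it. These differences between days were not tested.

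In the knockout, epidermis and surface ectoderm genes had a median log2 ratio of 1.33 on day 6 and -0.48 on day 10, where the latter lay inside the random range with no filter (-0.16), and Cdx2, a caudal regulator, 3.98 and -1.51. With overexpression, fibroblast and matrix genes had medians of 0.31 on day 4 and -2.26 on day 7, and posterior Hox genes 0.24 and -1.76. T had a log2 ratio of -5.17 on day 4 and 1.31 on day 7 with overexpression. Among all list members above the filter, 5 genes changed so in the knockout, 3 with Dkk and 9 with overexpression. T, which the rule does not name for the knockout, had log2 ratios of 3.19 on day 6 and -1.58 on day 10 there. With overexpression 6 of the 9 are primitive streak and early mesoderm genes, T, Mixl1 (-2.88 and 2.23), Eomes (-1.93 and 1.99), Gsc (-1.88 and 2.06), Fgf8 (-4.02 and 1.62) and Lhx1 (-2.04 and 1.92), of which all but T were chosen after their values were seen.

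The overexpressing culture differed from control in 643 genes on day 4 and in 2239 on day 7. Depth argues against counting noise as the reason, because both day 4 libraries are deeper than their day 7 counterparts and 2181 genes on day 7 against 608 on day 4 remained with a counting interval that excludes equality. A candidate explanation is that the overexpressing culture advanced less between the days than the control. The 1426 genes at least 2-fold higher on day 7 than on day 4 in control, with a median log2 change of 1.63, had a median of 0.33 in overexpressing cells, with quartiles of 0.01 and 0.74, and 258 of them were at least 2-fold higher there. These genes were picked by the control's own ratio, which raises its median by an amount that was not estimated, so whether the overexpressing culture advanced less stays open.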

How the results depend on the processing

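All alternatives were chosen before the data were examined. With 1 library per condition and day, no replicate could be left out, and depth limits genes with few reads most. In the knockout, Dkk and overexpression comparisons, 75 of 140 list medians lay outside the random range, where 7.0 are expected of random lists. Of these 75 medians, 75 kept their call with median-ratio scaling, 73 with a pseudocount of 0.1, 72 with a pseudocount of 1, 68 with no filter, and 61 of 71 with a filter of 5 RPKM, and 0 took the opposite call. Median-ratio scaling divides each library by 1 factor, which shifts a list and its random lists alike apart from the pseudocount. The calls kept under it, here and below, were nearly fixed in advance and do not check the normalization. The lists that lost a call are named beside their results. Of 17 such medians of the Dkk-treated knockout against wild type, 17 kept their call with median-ratio scaling and with a pseudocount of 1, 16 with a pseudocount of 0.1 and with no filter, and 14 with a filter of 5 RPKM, where pluripotency genes on day 6 took the opposite call (0.37 against -0.50) and the cause was not tested. The day 6 knockout median of the endothelium and blood list became -0.012 with the filter of 5 RPKM, against 0.60. Of 2022 values of named genes under the other pseudocounts and median-ratio scaling, 1951 stayed within counting error. A fixed tolerance was used where the counting interval had no finite limit. A total of 0 reversed, but reversal was counted only for changes of 2-fold or more. Neither a pseudocount nor these scaling factors could turn such a change, so that count was fixed in advance. Of 224 values of the main counts and tests under alternatives, 138 stayed close to the reported value, and the others follow.

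A 4-fold threshold lowers counts by construction. It left 187 genes higher and 45 lower in the knockout on day 6, 260 and 38 on day 10, and 62 and 3 on both days. With Dkk it left 55 higher and 140 lower on day 6, 50 and 153 on day 10, and 10 and 38 on both days. With overexpression it left 17 higher and 59 lower on day 4, 116 and 403 on day 7, and 7 and 5 on both days. A filter of 5 RPKM, under which fewer genes are compared, left 370 higher and 180 lower in the knockout on day 6, 643 and 135 on day 10, and 24 lower on both days. With Dkk it left 178 and 269 on day 6 and 100 and 371 on day 10, and with overexpression 129 and 286 on day 4 and 523 and 884 on day 7. Requiring a counting interval that excludes equality left 31 genes lower in the knockout on both days.

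A smaller pseudocount widens ratios of genes with low values. With 0.1, 542 genes were lower in the knockout on day 6, and 453 were higher and 101 lower on both days. With Dkk 471 were higher on day 6, and 78 were higher and 320 lower on both days. With overexpression 669 were lower on day 4, and 157 were higher and 232 lower on both days. A pseudocount of 1 gave 31 genes lower on both days in the knockout and 72 with overexpression. TPM scaling gave 469 lower in the knockout on day 6, 77 lower on both days, and 178 lower on both days with overexpression, and the cause was not tested.

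Genes higher in the knockout on day 6 had a median Dkk change on day 10 of -0.80 with a pseudocount of 0.1 and -0.88 with a filter of 5 RPKM. Genes lower on day 10 had a Dkk median on day 6 of 0.058 with that filter, outside the matched range. Genes higher in the knockout on both days had an overexpression median on day 4 of -0.23 with a pseudocount of 0.1 and -0.24 with the filter of 5 RPKM, both outside the matched range, and on day 7 of -1.08 with no filter and -1.77 with the filter of 5 RPKM. Genes lower on both days had a day 4 median of 0.47 with a pseudocount of 0.1, 0.11 with no filter and 0.20 with median-ratio scaling, all outside the matched range. On day 7 theirs was 1.18 with a pseudocount of 0.1, and 0.14 with a pseudocount of 1, inside it. The cause was not tested.

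The additive limma model called, higher and lower by knockout, 9 and 1 genes with a pseudocount of 0.1, 0 and 0 with no filter, 15 and 1 with a filter of 5 RPKM, 28 and 2 with a trend in the prior variance, and 103 and 10 in the SFEB culture alone. By Dkk it called 3 and 5, 0 and 0, 4 and 15, 2 and 16, and 9 and 37 in the same order, and 4 and 15 with a pseudocount of 1. By overexpression it called 0 and 2, 18 and 12, 14 and 12, and 6 and 7, and 0 and 0 in the FBS culture alone. At an unadjusted p under 0.05 the model held 2276 genes for knockout and 1110 for Dkk with no filter, 2337 for overexpression with a pseudocount of 0.1, and 1208 for overexpression in the FBS culture alone. The prior degrees of freedom were 0.44 with no filter against 2.73 in the reported model, and the cause of these differences was not tested.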

Other observations

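All lists and tests in this part were chosen after the results were seen, and the lists hold genes that prompted them, so their percentiles describe these libraries and are no independent evidence. Retinoic acid pathway genes (19 listed, 16 above the filter in SFEB, 0 in another list) had median log2 ratios of 1.09 and 1.04 in the knockout, with 8 and 9 members at least 2-fold higher, and of -1.43 and -1.40 with Dkk. Rarb, a receptor gene that retinoic acid induces, went from 1.73 RPKM in wild type to 13.7 in the knockout and 1.05 with Dkk on day 6, and through 1.36, 19.5 and 1.45 RPKM on day 10. Forebrain and midbrain patterning genes (26 listed, 22 above the filter, 8 in another list) had medians of -1.36 and -0.77 in the knockout and of 2.18 and 2.22 with Dkk. In the Dkk-treated knockout they stood above wild type, at 0.80 and 1.35, with 8 and 13 of 22 members at least 2-fold higher. Paraxial mesoderm and somite genes (20 listed, 18 above the filter, 9 in another list) had a median of 2.05 in the knockout on day 6, with 16 members higher, and of 0.41 on day 10, inside the random range at percentile 77.4.

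Trophoblast genes (21 listed, 9 above the filter in SFEB, 3 in another list) had medians of -1.25 and -1.93 in the knockout without Dkk and -1.25 and -1.88 with it, all against wild type. On day 6, 5 of 9 were at least 2-fold lower and 1 higher without Dkk, and 5 lower and 0 higher with it, and on day 10, 7 were lower and 0 higher in either condition. Ctsj was at 14.1 RPKM in wild type on day 10, 0.22 in the knockout and 0.48 with Dkk, and Prl7d1 at 7.06 and 0.67 RPKM in wild type and with Dkk and listed at 0 in the untreated knockout. Metallothionein and zinc transport genes (6 listed, 5 above the filter, 0 in another list) had medians of 1.31 and 1.81 with overexpression in FBS.

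The Dkk-treated knockout differed 2-fold from wild type in 330 genes on day 6 and 810 on day 10, and from the untreated knockout in 743 and 895, and 3 technical explanations of its nearness to wild type, slight on day 10 by these counts, were weighed. For wild-type libraries under a wrong name, 102 genes were at least 2-fold from wild type in the same direction on both days in the Dkk-treated knockout. Independent lists would give 11.5, but an excess over that product is a description and not a test, so it does not exclude this explanation. Morf4l2, described below and picked after its values were seen, stood at 260.7 and 225.6 RPKM with Dkk, against 36.3 and 37.1 in wild type. In 35 genes both knockout conditions differed from wild type on both days, though part of that count may come from the shared wild-type libraries. The untreated knockout library shared by both ratios does not enter the median Dkk change of -0.63 on day 10 of genes chosen on day 6, and the greater depth of the day 10 Dkk library has no part in the posterior Hox median of -3.30 on day 6, where depths were about equal. An action of Dkk in the knockout culture stays open as a hypothesis, with 1 culture per day and no wild-type cells given Dkk analysed here.

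Morf4l2, a gene on the X chromosome that encodes a chromatin protein, differed between the lines in both cultures. It was at 36.3 RPKM in wild type, 207.5 in the knockout and 260.7 with Dkk on day 6, and at 37.1, 225.7 and 225.6 RPKM on day 10. In FBS it was at 214.6 in control and 23.1 in overexpressing cells on day 4 and at 230.3 and 20.6 RPKM on day 7.

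Of 13757 genes, 2 were at least 2-fold higher in both knockout conditions on both days and 2-fold lower with overexpression on both days, Morf4l2 and the gene next to it in the RefSeq order, Tceal1. Among genes above the filter in SFEB, Ctsj and Dppa4 showed the mirror image, at least 2-fold lower in both knockout conditions and higher with overexpression on both days. If Morf4l2 reads had been assigned to its paralog Morf4l1 in overexpressing cells, Morf4l1 would rise there. Instead Morf4l1 changed by -21.6 RPKM with overexpression on day 4 and -12.8 on day 7, while Morf4l2 changed by -191.6 and -209.7 RPKM. This was computed for the FBS culture only, and other ways of sharing or dropping reads between the paralogs were not tested. A difference of this chromosomal neighbourhood between the lines may account for the pair and cannot be told apart from an effect of Tet3. Of 10 expressed neighbours within 25 places, 2 (Tceal1 and an unnamed clone, on either side) share the signs of Morf4l2, against 10.0% of all genes (Fisher's exact test, two-sided, p = 0.264). The clone had log2 ratios of 1.55 and 1.81 in the knockout, 1.66 and 1.68 with Dkk against wild type, and -1.31 and -0.97 with overexpression. Its values were low, at most 1.36 RPKM. The test counts signs alone and does not weigh nearness, so it cannot decide about the adjacent genes.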
